A study of Homo sapiens with 7 samples.

How the data were processed

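Candidate regulatory sequences were cloned with barcodes into a lentiviral reporter library, the library was transduced into C4-2B cells, and gDNA and RNA were extracted together 48 hours later, per the labels' protocols. The series has 7 libraries, 1 for the association of barcodes with sequences, 3 of gDNA and 3 of RNA, and the gDNA fraction served to normalise the RNA fraction, per the labels. Bowtie2 and hg38 are named in the submitters' processing notes, without a role or version. Read trimming, barcode filters, the number of barcodes per construct, the length and placing of the constructs and the exact form of the model are not given in the sources used here. Neither is the scrambled sequence that each wild-type construct was compared with.

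The analysis started from 2 tables of comparisons that the authors deposited, 1 for wild-type against scrambled sequence (358 constructs) and 1 for mutant against wild-type sequence (1025 constructs). The estimate is a log odds ratio on the natural log scale from a logit model, per the file headers. The model's z value, a score, was deposited by the authors beside each estimate. A p-value and a q-value were deposited by the authors for each construct. Recomputed here, the p-value equalled the two-sided normal p of z, and the q-value equalled the Benjamini-Hochberg adjustment over the table's constructs. The direction of each estimate was read from the way the authors named each table, so that a positive estimate means more RNA over gDNA for wild-type than scrambled, or for mutant than wild-type, and no other source used here states it. The standard error printed with an estimate is the estimate divided by z. A fold is the exponential of the estimate's size and is a fold of odds. The median standard error was 0.11 in the wild-type table (quartiles 0.08 and 0.20) and 0.12 in the mutant table (quartiles 0.08 and 0.20). The authors' model combined the replicates, and the tables give no counts, barcodes or values per replicate. The depth per library and per construct is therefore unknown, the spread between the 3 replicates could not be measured, and no count model was run. Estimates beyond 10 in size came with standard errors far larger than themselves, as from a fit without a bound. They numbered 5 in the wild-type table and 13 in the mutant table, and none was called.

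Coordinates come from the construct names in the tables. The start was raised by 1 base to count from 1, since 0 tested sites then fell before the start and 3 fell on the last base. Genes were assigned from a table of 19993 protein-coding genes of GRCh38.p14, the same build, by overlap with the gene body and otherwise by the nearest gene body on the chromosome. The plan was the nearest transcription start site, but the gene table used here has no strand, so starts could not be told from ends. Exons, introns and untranslated regions were not resolved for the same reason, and chromosome Y genes were left out. Of the 1025 mutant constructs, 146 carried an insertion or deletion and 879 a substitution. No base change or position of a mutation is printed.

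Before the data were examined, the tests, the gene lists, the named-gene rule and a list of alternatives were fixed. A construct was called at an adjusted p under 0.05. The rule named, in each table, the 10 constructs with the largest positive and the 10 with the largest negative estimate among those called, at most 1 per region, the one with the smallest p. It also named called constructs of the gene lists, and the region at SF3A1 whatever its values. Constructs of IL3RA, CIAO3, HAS3, CCT3, WASF2, NCAM1 and of regions with calls of 1 direction were named after their values were seen, as were uncalled constructs of the gene lists. The 6 lists were androgen receptor targets and prostate lineage genes, genes recurrently altered in prostate cancer, neuroendocrine genes, splicing genes, cell cycle and DNA replication genes, and ribosomal proteins. Lists were compared with all other constructs by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over lists and tables. The plan named regions as the unit of these tests, but constructs were counted. The result of the list of genes recurrently altered in prostate cancer is not reported here.

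Higher and lower calls were compared by two-sided exact binomial tests with exact Clopper-Pearson intervals. Relations across regions used Spearman's rho and Pearson's r with 100000 permutations. Same-sign shares were set against 100000 shuffles of the signs, or 10000 where calls were shuffled over regions. Intervals of covariances, ratios and neighbour correlations come from 2000 bootstrap draws over regions. Because both tables use wild-type reads, taken here to be those of the construct of the same name, 1000 draws without any effect were simulated in which the wild-type reads carried 50% of the smaller squared error of each pair. The simulation was run with the deposited errors and with errors multiplied by the robust SD of z (4.12 and 3.92). The settings tried, fixed before the data were examined, were thresholds of 0.01 and 0.1, Bonferroni adjustment, an empirical null (z centred on its median and divided by its robust SD), centred estimates, a minimum effect, other summaries of a region, and constructs in place of regions for the share of called mutants. A filter on low coverage, leaving out each replicate and a fit with the replicate as a block were also intended and not run, since the tables lack the values they need. Added after the data were seen were the correlations and same-sign share without unbounded estimates, the correlations over single constructs, and gene lists with every gene within 100 kb.

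The calling step was tested on simulated z values. With 1025 constructs of which 200 were shifted by 3 noise units, the normal null recovered 48% of the shifted constructs with 3.03% false calls. The empirical null recovered 6.5% of them, and 94.5% of constructs shifted by 5 noise units. With the noise 3.92 times wider than the normal null assumes, 71.1% of its calls were false, and the empirical null recovered 20% of constructs shifted by 3 noise units and 95.5% of those shifted by 5. For the wild-type table, with 358 constructs of which 70 were shifted by 3 noise units, the normal null recovered 64.3% with 4.26% false calls. The empirical null recovered 5.71% of them, and 90% of constructs shifted by 5 noise units. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.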

Results

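The study placed candidate regulatory regions of the human genome in a lentiviral massively parallel reporter assay (lentiMPRA) and read their activity in C4-2B cells, an established human prostate cancer line derived from a bone metastasis of the LNCaP lineage. In this assay each candidate sequence drives a barcoded transcript after integration, and the barcode reads in RNA are set against those in genomic DNA (gDNA). The series held 7 libraries, of which 1 linked barcodes to candidate sequences, 3 were gDNA and 3 were RNA, the last 6 extracted 48 hours after transduction. Activity was analysed from 2 of the authors' deposited tables, 1 comparing wild-type sequence with scrambled sequence and 1 comparing mutant with wild-type sequence. Each gives 1 estimate per construct, taken here as the natural log of an odds ratio of RNA over gDNA. The estimate is printed with the standard error that it and its z value imply. Read from the names in the tables, a construct is a sequence that carries 1 tested mutation of a region, or its wild-type counterpart. The tables carry no read, barcode or replicate values, so the depth behind each estimate is unknown and the p-values measure only the error of the authors' model. The tables covered 380 regions, of which 203 lay inside a protein-coding gene, 164 were intergenic and 13 overlapped a gene end. Regions are named by the overlapping or nearest protein-coding gene, in hg38 coordinates. Such a name does not state that the region controls the gene. A construct is called higher or lower below where the authors' adjusted p was under 0.05.

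The first comparison asked which wild-type regions drove more or less reporter RNA than scrambled sequence. A region 299 bp from MCPH1, which encodes the DNA damage response protein microcephalin, had the smallest p in the authors' deposited table, with an estimate of 1.33 ± 0.06, or 3.80-fold higher odds (chr8:6648807-6650052, adjusted p = 1.02e-117). All 6 wild-type constructs of the MCPH1 region were called higher in the authors' deposited table, from 1.70- to 30.8-fold. A construct of a region 282 bp from F11R, the gene of junctional adhesion molecule A, had an estimate of 1.42 ± 0.11 in the authors' deposited table, or 4.13-fold (chr1:161021434-161026093, adjusted p = 3.2e-36). A construct of the region inside SKAP1, which encodes a T-cell adaptor protein, stood at -1.12 ± 0.08 in the authors' deposited table, or 3.08-fold lower odds (chr17:48156513-48159961, adjusted p = 3.05e-45).

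With 1 construct taken per region, the one with the smallest p, the highest called estimates in the authors' deposited table belonged to constructs of regions inside UBASH3A, a regulator of T-cell receptor signalling, at 2.98 ± 0.75, and UCKL1, a uridine kinase family gene, at 2.74 ± 0.66. These are 19.7- and 15.4-fold higher odds in the authors' deposited table (chr21:42440843-42441892 and chr20:63953376-63953727). A construct of a region inside TMEM132C followed at 2.24 ± 0.36, or 9.44-fold, in the authors' deposited table (chr12:128294180-128296178, adjusted p = 4.01e-09), while the other TMEM132C construct was called lower at -0.54 ± 0.10. Regions inside TECPR2, an autophagy gene, and MICAL3, a monooxygenase gene, stood at 1.45 ± 0.44 and 1.44 ± 0.43 in the authors' deposited table. The authors' deposited table placed a construct of a region 5764 bp from NRARP, a feedback inhibitor of Notch signalling, at 1.42 ± 0.39. The same authors' deposited table gave 1.36 ± 0.33 for a construct of a region inside NRG1, which encodes a ligand of the ERBB3 and ERBB4 receptors (chr8:32258967-32261520). A construct of a region 934 bp from RAB6A, a Golgi transport GTPase, stood at 1.21 ± 0.20 in the authors' deposited table. The other RAB6A wild-type construct was at 0.01 ± 0.10, not called. The UBASH3A, NRARP, F11R and NRG1 regions each also held 1 wild-type construct called lower in the authors' deposited table, beside 1, 3, 4 and 4 called higher. The lower NRG1 construct stood at -3.75 ± 1.08 in the authors' deposited table, larger in size than the NRG1 value above but with a larger p.

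At the other end of the authors' deposited table, a construct of the region inside PMP22, which encodes a myelin protein, stood at -2.83 ± 0.65, or 17.0-fold lower odds than scrambled sequence (chr17:15244517-15246939). The other PMP22 wild-type construct was called higher at 0.63 ± 0.16 in the authors' deposited table (adjusted p = 0.000311). A construct of the region inside TIMELESS, a replication fork gene, stood at -2.50 ± 0.47, or 12.2-fold lower, in the authors' deposited table (chr12:56447920-56449062). The only wild-type construct of a region 42844 bp from the developmental regulator EYA1 stood at -2.46 ± 0.42, or 11.7-fold lower, in the authors' deposited table (chr8:71590938-71592202). Constructs of the regions inside the zinc finger gene ZNF276 and 13845 bp from MACIR had estimates of -1.96 ± 0.34 and -1.70 ± 0.28 in the authors' deposited table. Other constructs there were called higher in the authors' deposited table, 1 at ZNF276 at 0.37 ± 0.10 and 2 at MACIR at 0.88 ± 0.20 and 1.59 ± 0.39. Regions inside CGN, which encodes the tight junction protein cingulin, PEX5L and the sodium channel gene SCN9A had constructs at -1.64 ± 0.34, -1.60 ± 0.37 and -1.40 ± 0.20 in the authors' deposited table. The other PEX5L wild-type construct was at 0.29 ± 0.24, not called, and SCN9A had 1 wild-type construct in all. The CGN region had 2 constructs called lower and 1 higher, and the SKAP1 region 3 called lower and 1 higher, in the authors' deposited table. The region over an end of TTLL3 and ARPC4-TTLL3 stood at -1.18 ± 0.17 in the authors' deposited table, and 3 of its 3 constructs were called lower (chr3:9836314-9837354, adjusted p = 1.19e-11).

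**Figure D1:**
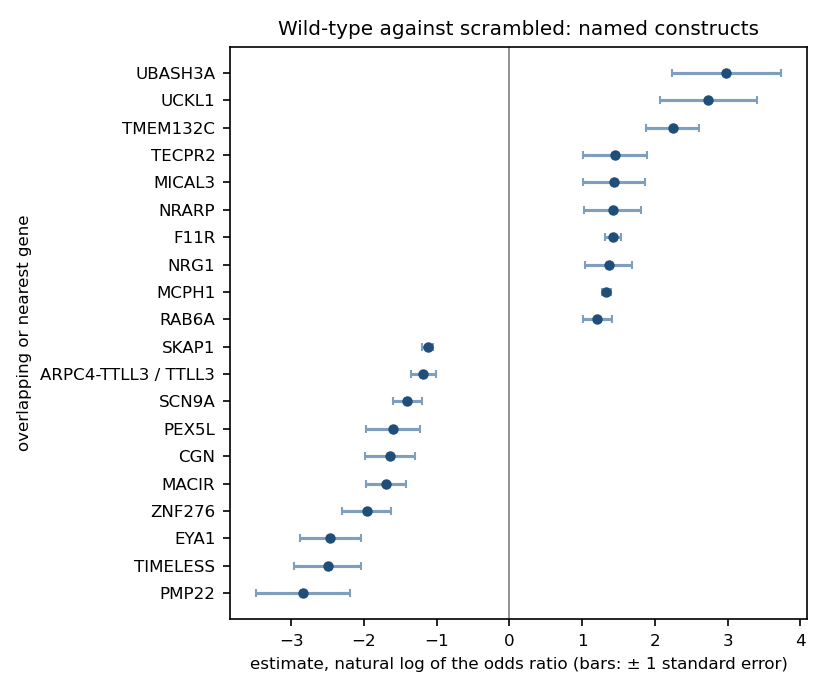
Estimate of each named wild-type construct against scrambled sequence, on the horizontal axis as the natural log of the odds ratio from the authors' deposited table, with bars of ± 1 standard error. The named constructs run from -2.83 at PMP22 to 2.98 at UBASH3A, and MCPH1, SKAP1 and F11R have short bars.

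In all, 223 of 358 wild-type constructs (62.3%) were called in the authors' deposited table, 122 higher and 101 lower, and 135 were not. At an unadjusted p under 0.05 the count in the authors' deposited table was 231. The called constructs lay in 81 of 91 regions, of which 21 held higher calls only, 21 held lower calls only and 39 held both directions. The median size of a called estimate was 0.51 in the authors' deposited table, or 1.67-fold, with quartiles of 0.31 and 0.86. Higher calls made up 54.7% of the calls (95% exact interval 47.9 to 61.4%, two-sided exact binomial p = 0.180, 0.340 after adjustment over both tables), with constructs of a region not independent of each other. The z values of the authors' deposited table had a robust SD of 4.12, and with z scaled by that spread 4 constructs were called, 1 each at MCPH1, SKAP1, IL3RA and CIAO3. Bonferroni adjustment left 120 calls. Among constructs named for the highest or lowest estimates, it ended the calls at TECPR2, MICAL3 and NRARP. Among constructs of the gene lists, it ended the calls at 1.20 ± 0.42 and 1.86 ± 0.51 at SF3A1. It also ended the call at -0.19 ± 0.08 at NDRG1.

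The second comparison asked which mutations changed the activity of a region relative to its wild-type sequence. Among called mutants, with 1 taken per region, the highest estimate in the authors' deposited table lay in a region inside RRAGD, which encodes a GTPase of amino acid sensing by mTORC1, at 4.24 ± 1.13, or 69.6-fold higher odds (chr6:89371867-89373220, adjusted p = 0.000523). The lowest among called mutants lay in a region inside MAP1LC3B, an autophagosome gene, at -4.11 ± 1.14, or 60.7-fold lower, in the authors' deposited table (chr16:87396942-87400020, adjusted p = 0.000855). Among the 10 lowest named mutants, the smallest standard error belonged to one 8867 bp from NOM1, a nucleolar protein gene, at -2.19 ± 0.16, or 8.91-fold lower, in the authors' deposited table (chr7:156939722-156940845, adjusted p = 2.33e-38). The NOM1 region also held 1 mutant called higher, at 2.89 ± 0.59 in the authors' deposited table, larger in size but with a larger p. A mutant 213004 bp from SATB1, a chromatin organiser gene, stood at -2.09 ± 0.26, or 8.10-fold lower, in the authors' deposited table (chr3:18658596-18658836).

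Other mutants with higher activity than wild-type lay inside FCHSD2, an endocytosis gene, at 3.34 ± 0.68, and inside ZNF577 at 2.87 ± 0.61, in the authors' deposited table (chr11:72884513-72892993 and chr19:51860243-51863236). A mutant inside IL36RN, which encodes the interleukin-36 receptor antagonist, reached 2.53 ± 0.48, or 12.6-fold, in the authors' deposited table (chr2:113058663-113058740, adjusted p = 6.92e-07). Mutants inside PMP22 and the adhesion molecule gene OPCML reached 2.36 ± 0.68 and 2.32 ± 0.68 in the authors' deposited table, and one 525 bp from NECAB1, a calcium-binding protein gene, reached 2.17 ± 0.41. Mutants inside TIMELESS, ZNF276 and OBSL1 reached 2.10 ± 0.54, 2.06 ± 0.36 and 2.04 ± 0.40 in the authors' deposited table. The TIMELESS and ZNF276 regions each also held 1 mutant called lower in the authors' deposited table, at -0.67 ± 0.22 and -0.43 ± 0.10. The regions at RRAGD, IL36RN, OPCML and OBSL1 each held 1 mutant in all. The regions at PMP22, TIMELESS and ZNF276 also held constructs among the 10 lowest named wild-type constructs against scrambled sequence.

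Among mutants with lower activity, one lay 6721 bp from NID2, a basement membrane gene, at -3.77 ± 0.72, or 43.4-fold lower, in the authors' deposited table (chr14:52075780-52083113, adjusted p = 8.2e-07). Another, 116558 bp from ZNF366, stood at -3.22 ± 0.63 in the authors' deposited table, and one 448 bp from the nuclear pore gene NUP85 stood at -2.97 ± 0.53 (chr17:75204248-75205231). Of the 11 mutants in the NUP85 region, 2 were called higher, 2 lower and 7 neither in the authors' deposited table. A mutant 8694 bp from TNFSF10, the gene of the death ligand TRAIL, stood at -2.69 ± 0.86 in the authors' deposited table. Mutants inside HARS1, the histidyl-tRNA synthetase gene, and TPCN2, an endolysosomal channel gene, stood at -2.62 ± 0.36 and -2.29 ± 0.33 in the authors' deposited table (adjusted p = 6.4e-12 and 7.18e-11). The RAB6A region had a mutant at -2.27 ± 0.48, or 9.69-fold lower, in the authors' deposited table. The NID2 and TPCN2 regions each also held 1 mutant called higher in the authors' deposited table, at 0.45 ± 0.12 and 0.48 ± 0.10. The ZNF366 and TNFSF10 regions, and the SATB1 region above, each held 1 mutant in all.

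**Figure D2:**
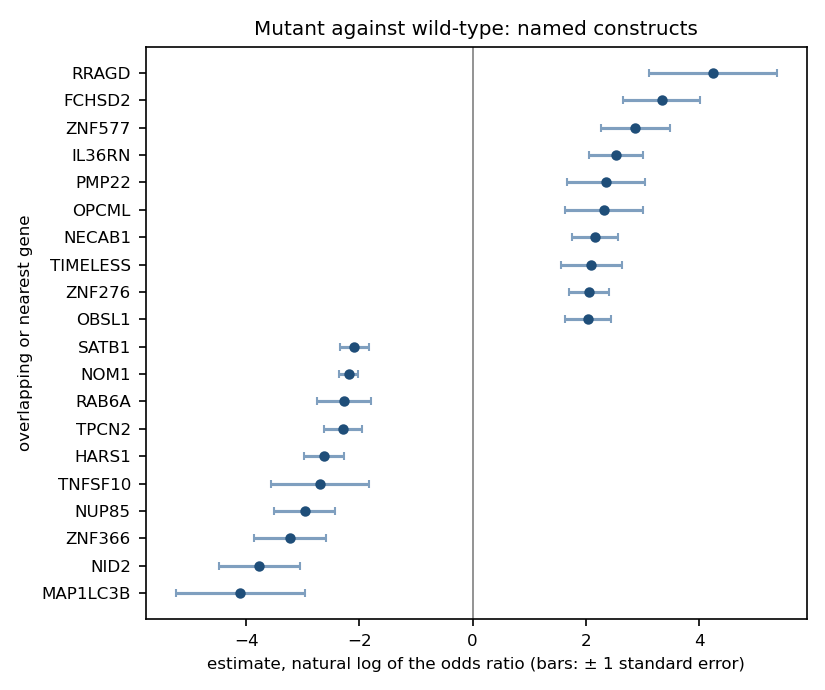
Estimate of each named mutant construct against its wild-type counterpart, on the horizontal axis as the natural log of the odds ratio from the authors' deposited table, with bars of ± 1 standard error. The largest estimates, 4.24 at RRAGD and -4.11 at MAP1LC3B, also have the widest bars.

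In all, 580 of 1025 mutant constructs (56.6%) were called in the authors' deposited table, 302 higher and 278 lower, and 445 were not, with 625 at an unadjusted p under 0.05. The calls lay in 282 of 376 regions, of which 105 held higher calls only, 94 held lower calls only and 83 held both. The median size of a called estimate was 0.53 in the authors' deposited table, or 1.70-fold, with quartiles of 0.33 and 0.91. Higher calls made up 52.1% (95% exact interval 47.9 to 56.2%, two-sided exact binomial p = 0.340). The z values of the authors' deposited table had a robust SD of 3.92, and with z scaled by that spread 2 mutants were called, at HAS3 and IL3RA. Bonferroni adjustment left 306 calls. Among mutants named for the highest or lowest estimates, it ended the calls at RRAGD, MAP1LC3B, PMP22, OPCML, TIMELESS and TNFSF10. Among mutants of the gene lists, it ended all calls at SF3A1 and that of the FOXA1 mutant at 0.66 ± 0.18.

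The region inside SF3A1, which encodes a subunit of the U2 spliceosome particle, was fixed for reporting before the data were examined because the study singled it out (chr22:30351639-30352714, within the gene at 30331988 to 30356894 and 3910 bp from CCDC157). Of its 4 wild-type constructs, 3 were called higher than scrambled sequence in the authors' deposited table, at 1.20 ± 0.42, 1.03 ± 0.08 and 1.86 ± 0.51, or 3.32-, 2.79- and 6.43-fold. The fourth wild-type construct stood at -0.16 ± 0.09 in the authors' deposited table and was not called (adjusted p = 0.117). Of the 5 SF3A1 mutants, 3 were called higher than wild-type in the authors' deposited table, at 0.39 ± 0.11, 0.19 ± 0.08 and 0.28 ± 0.09, or 1.48-, 1.20- and 1.32-fold. The other SF3A1 mutants, at 0.23 ± 0.12 and -0.03 ± 0.09 in the authors' deposited table, were not called (adjusted p = 0.106 and 0.829). None of the SF3A1 calls in either table was kept when z was scaled by its spread. With Bonferroni adjustment none of the mutant calls was kept, and of the wild-type calls only that at 1.03 ± 0.08 was kept.

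**Figure D3:**
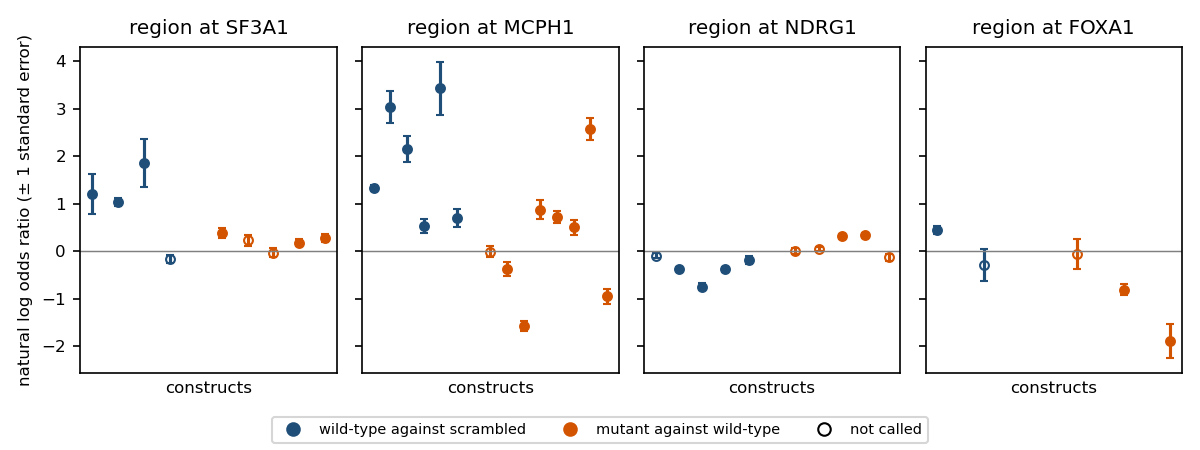
Estimates of all constructs in the regions inside SF3A1, NDRG1 and FOXA1 and near MCPH1, from the authors' deposited table. The region over an end of FOXA1 is not drawn. The vertical axis is the natural log of the odds ratio, with bars of ± 1 standard error. Blue marks wild-type against scrambled, orange marks mutant against wild-type, and open points were not called. All 6 wild-type constructs at MCPH1 lie above 0, while its 8 mutants include 4 called higher and 3 called lower.

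Among genes of the androgen receptor and prostate lineage list, the region inside FOXA1, the gene of a pioneer factor of the androgen receptor, had a wild-type construct called higher at 0.44 ± 0.08, or 1.56-fold, and another at -0.29 ± 0.34 that was not called, in the authors' deposited table (chr14:37589985-37591363). In that FOXA1 region 2 mutants were called lower than wild-type in the authors' deposited table, at -0.80 ± 0.11 and -1.89 ± 0.35, or 2.23- and 6.60-fold lower, and one at -0.05 ± 0.32 was not called. In a second region, over an end of FOXA1, 1 mutant was called higher at 0.66 ± 0.18 in the authors' deposited table, and one at -1.35 ± 0.70 was not called (chr14:37588594-37589983, adjusted p = 0.0887). The region inside NDRG1, an androgen-responsive gene, had 4 of 5 wild-type constructs called lower than scrambled sequence in the authors' deposited table, at -0.37 ± 0.04, -0.74 ± 0.08, -0.38 ± 0.05 and -0.19 ± 0.08 (chr8:133252343-133253812). At NDRG1 2 of 5 mutants were called higher than wild-type in the authors' deposited table, at 0.31 ± 0.06 and 0.34 ± 0.06. Over the list, 10 mutants in 3 regions gave 3 higher calls, 2 lower and 5 neither, and 7 wild-type constructs in 2 regions gave 1 higher, 4 lower and 2 neither. Adjusted over the list alone, 5 constructs were called in each table, as before.

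Of the splicing list, SF3A1 and HNRNPC were represented. The region 1064 bp from HNRNPC, which encodes a nuclear RNA-binding protein, had 2 of 6 mutants called higher in the authors' deposited table, at 0.53 ± 0.12 and 1.72 ± 0.38, or 1.70- and 5.58-fold (chr14:21270506-21270854). The splicing list had 11 mutants with 5 higher calls, 0 lower and 6 neither, and 4 wild-type constructs with 3 higher, 0 lower and 1 not called. Its SF3A1 members were singled out by the study, on a basis not given in the sources used here, and may not be independent evidence of direction. The neuroendocrine list had 1 mutant, inside NCAM1, at 0.50 ± 0.46 in the authors' deposited table and not called. The cell cycle and ribosomal protein lists had 0 constructs in either table. Adjusted over the list alone, the splicing list had 5 mutant and 3 wild-type calls and the neuroendocrine list 0. None of these lists differed from all other constructs in its share of calls (two-sided Fisher's exact test, adjusted p from 0.905 to 1), and lists of 1 to 11 constructs allow little precision. Constructs of a region are also not independent of each other, which these tests do not take into account.

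The next comparison asked whether mutations changed activity differently in regions of high and low wild-type activity. In the regions of ZNF577, PMP22, TIMELESS and ZNF276, the mutant among the 10 highest was above wild-type while the wild-type construct of the same name was lower than scrambled sequence. The wild-type estimates of those constructs were -2.79 ± 0.55, -2.83 ± 0.65, -1.73 ± 0.51 and -1.96 ± 0.34 in the authors' deposited table. The sum of both estimates was 0.08, -0.48, 0.37 and 0.10 for the same constructs. It would set the mutant against scrambled sequence if the mutant was compared with that wild-type construct, which is not stated in the sources used here. At NECAB1 the wild-type construct was at 0.07 ± 0.65 in the authors' deposited table, was not called, and the sum was 2.24. These are the 5 mutants among the 10 highest and 10 lowest whose wild-type construct has a row in the other table. All 5 were picked for a high estimate against wild-type. If the wild-type reads are shared, that choice favours wild-type constructs that deviate low. Opposite signs and small sums can then follow from the choice alone, so these 5 pairs do not answer the question. At SF3A1, called mutants at 0.39 ± 0.11 and 0.19 ± 0.08 had wild-type constructs also called higher in the authors' deposited table, at 1.20 ± 0.42 and 1.86 ± 0.51, with sums of 1.59 and 2.05. The third called SF3A1 mutant had a wild-type construct at -0.16 ± 0.09 in the authors' deposited table, not called, and a sum of 0.12. At NDRG1 both called mutants had wild-type constructs called lower in the authors' deposited table, at -0.74 ± 0.08 and -0.38 ± 0.05, with sums of -0.43 and -0.05. At FOXA1 the called mutants at -0.80 ± 0.11 and -1.89 ± 0.35 had wild-type constructs at 0.44 ± 0.08, called higher, and -0.29 ± 0.34, not called, in the authors' deposited table, with sums of -0.36 and -2.18.

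Across 87 regions in both tables, the mean mutant estimate fell as the mean wild-type estimate rose, with Spearman's rho of -0.223 (permutation p = 0.0375, 0.0556 after adjustment over 6 such correlations) and Pearson's r of -0.390 (permutation p = 0.0140, adjusted 0.0337). The 2 regions farthest from the median wild-type estimate were those at CCT3 and WASF2, both with estimates beyond 10 in size. Without them rho weakened to -0.167 (permutation p = 0.125) and r was 0.248 (permutation p = 0.0306), the opposite sign. Estimates beyond 10 in size remained in the means of other regions in that setting, such as the one at MICAL3. The sign of r there cannot be told apart from their influence. With every construct beyond 10 in size left out, 84 regions gave a rho of -0.329 (permutation p = 0.00227) and an r of -0.274 (permutation p = 0.0168). Over 316 constructs with bounded estimates in both tables, rho was -0.354 and r was -0.434 (permutation p = 1e-05 each, the smallest that 100000 permutations can give, with constructs of a region not independent), and both of these alternatives were added after the data were seen. Where both estimates use the same wild-type reads, these enter with opposite sign, and a negative relation arises with no effect. In a simulation over the same 316 constructs with no effect and the deposited errors, rho was -0.325 (95% of draws from -0.434 to -0.219). The observed rho of -0.354 over constructs lies within that range. The simulated covariance was -0.0128, against an observed covariance of -0.243 (95% bootstrap interval -0.396 to -0.121). With errors widened to the spread of z, the simulated covariance was -0.204 (95% of draws from -0.442 to -0.0592). Both simulations rest on the 50% share of error given to the wild-type reads, and no other share was run.

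Of the 130 constructs called in both tables, 100 had opposite directions. In 49 the mutant was higher and the wild-type lower, in 51 the reverse, in 18 both were higher and in 12 both were lower. Independent calls would give 28.8, 32.4, 34.1 and 27.4. The simulation with widened errors and no effect gave 75.5% opposite directions among constructs called in both, against 76.9% observed. The simulated percentage depends on the 50% share given to the wild-type reads, and the widened errors count all spread of z as noise. The near match therefore does not show that noise alone made the pattern.

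**Figure D4:**
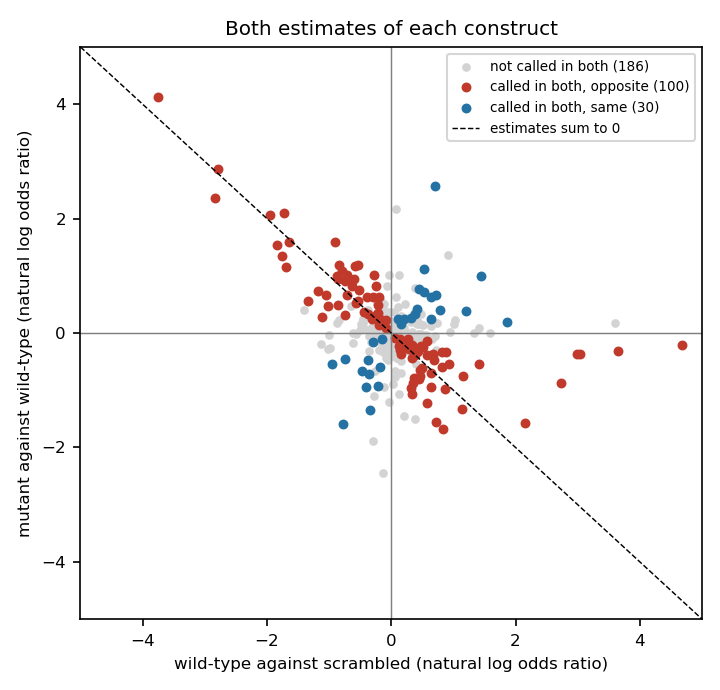
Each point is 1 of 316 constructs, with its wild-type estimate against scrambled sequence on the horizontal axis and its mutant estimate against wild-type on the vertical axis, both as natural log odds ratios. The 100 constructs called in both with opposite directions are red, the 30 with the same direction are blue, and on the dashed line both estimates sum to 0.

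Regions with a called wild-type construct more often held a called mutant. SF3A1, MCPH1, NDRG1 and FOXA1 were among the 78 regions with a called wild-type construct, of which 70 (89.7%) held a called mutant, against 4 of 9 other regions (44.4%), an odds ratio of 10.9 (two-sided Fisher's exact p = 0.00311). The 78 regions had a median of 4 wild-type constructs and 4 mutants, and the 9 a median of 1 and 2, so both the grouping and the chance of a called mutant follow the number of constructs. Counted by construct, 130 of 205 mutants (63.4%) were called where the wild-type construct of the same name was called and 61 of 119 (51.3%) where it was not, an odds ratio of 1.65 (two-sided Fisher's exact p = 0.0354). Constructs of a region are not independent of each other, which this p-value does not take into account. The simulation with widened errors and no effect gave an odds ratio of 1.24 by construct, under the same assumptions on the errors.

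The last comparison asked whether mutants of a region acted alike. At MCPH1 the 8 mutants ran from -1.57 ± 0.11 to 2.57 ± 0.23 in the authors' deposited table, with 4 called higher and 3 lower. At NOM1 the 5 mutants ran from -2.19 ± 0.16 to 2.89 ± 0.59 in the authors' deposited table. At RHBG, which encodes an ammonium transporter, 3 of 3 mutants were called lower in the authors' deposited table, from -0.73 ± 0.27 to -0.44 ± 0.12 (chr1:156383227-156384845). Over 1879 pairs of mutants in 225 regions, 49.8% had the same sign, against 50.1% after shuffling (permutation p = 0.802). If the mutants of a region shared 1 wild-type sequence that held 50% of the variance, a simulation with no effect gave 66.8%. Which wild-type construct the authors used for each mutant is not given in the sources used here.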

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

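The correlations and same-sign share without unbounded estimates, the correlations over single constructs and the gene lists with every gene within 100 kb were chosen after the results were seen. The number of calls depended on the null distribution and the correction. With Bonferroni adjustment 306 mutant and 120 wild-type constructs were called, in place of 580 and 223, and with the empirical null 2 and 4. Of the 20 constructs of each table named for the highest or lowest estimates, Bonferroni adjustment kept 14 mutant and 17 wild-type constructs. The empirical null kept 0 and 2 of these. These counts leave out the constructs named from the gene lists. Of those, Bonferroni adjustment also ended mutant calls at SF3A1 and FOXA1 and wild-type calls at SF3A1 and NDRG1. The empirical null counts the spread of most constructs as noise, so it loses true effects where most constructs carry one. It also lost most smaller effects in simulated z values with 200 of 1025 constructs shifted and noise as the normal null assumes. Of constructs shifted by 3 noise units it recovered 6.5%, against 48% for the normal null. Its few calls therefore do not measure how many effects are real. The cause of the wide z values was not tested. Thresholds of 0.01 and 0.1 gave 492 and 648 mutant calls and 175 and 241 wild-type calls. Centring kept the authors' adjusted p, so it could change only the direction of a call and not the number of calls. It moved no call across 0. The relation of mutant to wild-type estimates across regions weakened to a rho of -0.167 without the regions at CCT3 and WASF2, whose means rest on unbounded estimates. It was -0.215 with the mutant of smallest p, -0.260 in called regions and -0.329 without unbounded estimates, while Pearson's r was 0.164, -0.157 and -0.274 under these, and 0.248 without CCT3 and WASF2, against -0.390 as reported. Of these settings, only the one without unbounded estimates removed all such estimates from the region means. The odds ratio of calls by wild-type activity ran from 1.65 by construct to 6.13 at a threshold of 0.01 and 10.9 as reported. The balance of calls, the same-sign share of mutants and the gene lists stayed on the same side of the threshold under each alternative run. No paired analysis was possible because the tables hold no values per replicate. For the same reason leaving out each replicate and a filter on low coverage were not run, and the depth behind each estimate limits all of these results by an unknown amount.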

Other observations

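All tests below except the correlation with another wild-type construct were chosen after the results were seen, and so were the regions named here. The most extreme z value of the mutant comparison was a mutant inside HAS3, a hyaluronan synthase gene, at -1.61 ± 0.06, or 5.00-fold lower, in the authors' deposited table (chr16:69102541-69105037, adjusted p = 9.43e-138). It was the only mutant of its region. A region 386 bp from IL3RA, which encodes the interleukin-3 receptor alpha chain, had a mutant at -1.32 ± 0.08 and a wild-type construct of the same name at 1.14 ± 0.08 in the authors' deposited table, with a sum of -0.19 (chrX:1334602-1336399). Of 8 wild-type constructs in the IL3RA region 5 were called higher and 2 lower, and of 8 mutants 1 was called higher and 4 lower in the authors' deposited table. A region 334 bp from CIAO3, a cytosolic iron-sulfur assembly gene, had a wild-type construct at -1.12 ± 0.06, or 3.07-fold lower than scrambled sequence, in the authors' deposited table (chr16:741331-741695).

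Some regions held calls of a single direction in at least 1 of the tables. At ZNF544 3 of 4 mutants were called higher, from 0.79 to 1.25, or 2.20- to 3.49-fold, in the authors' deposited table (chr19:58261635-58262753), while none of its 3 wild-type constructs was called. In a region at AREL1, a ubiquitin ligase gene, 3 of 4 mutants were called lower, from -0.63 to -0.42, in the authors' deposited table (chr14:74710748-74711757). Another AREL1 region had mutants at -0.26 ± 0.15 and 0.15 ± 0.08, neither called (chr14:74706937-74708143). The region inside the kinesin light chain gene KLC4 had 3 of 4 wild-type constructs called higher, from 0.32 to 0.58, while of its 4 mutants 3 were called lower and 1 higher, in the authors' deposited table (chr6:43067399-43069397). The 3 lower KLC4 mutants have the same names as its 3 higher wild-type constructs, so these calls are not separate observations if the wild-type reads are shared. At LRCH3 3 of 3 wild-type constructs were called higher in the authors' deposited table, from 0.36 ± 0.11 to 4.68 ± 1.24 (chr3:197792365-197794253). Among regions with 3 or more calls, 6 of 36 wild-type and 14 of 74 mutant regions had a single direction, against 5.45 and 11.2 after shuffling the calls. Shuffling gave as many in a share of 0.468 and 0.219 of 10000 permutations (one-sided permutation p), so a chance arrangement of calls may account for these numbers, and no biological explanation was tested.

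The opposite signs of mutant and wild-type estimates could come from a wild-type construct shared by both. Counting error alone, as the authors' model states it, was too small, since the covariance was 9.60 times the most that the deposited errors allow (95% bootstrap interval 6.29 to 12.2). A second candidate explanation is that single wild-type constructs deviate, from a few barcodes for example, by more than the deposited errors. Over 158 pairs in 41 regions, the mutant estimate had a rho of -0.400 (95% bootstrap interval -0.548 to -0.229) with its own wild-type construct and -0.112 (-0.279 to 0.063) with another wild-type construct within 20 bp. Neighbouring wild-type constructs themselves had a rho of only 0.165 (-0.097 to 0.398), so this test could not decide, and deviation of single constructs stays open, as does the possibility that mutations bring activity back towards the scrambled level, which sums made from the same wild-type estimates do not test.

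Wild-type constructs within 20 bp of each other could be expected to have like estimates if they share most of their sequence and the scrambled sequence they were compared with. Neither the construct length nor the scrambled sequence of each comparison is given in the sources used here. Unlike estimates of neighbours can therefore come from either side of the comparison. Of 41 pairs with both called, 25 had the same sign, or 61.0% (95% bootstrap interval 46.9 to 76.5%, permutation p = 0.198), a range that includes both chance and the 75% set as the bound for shared sequence, so the called pairs are too few to decide. Over all 83 wild-type pairs within 20 bp, called or not, 51.8% had the same sign, against 49.6% after shuffling (permutation p = 0.741). At 3 regions a pair of wild-type constructs was tied to a single position. Their estimates were 0.78 ± 0.12 and -0.77 ± 0.12 at P2RY8, 0.88 ± 0.20 and -1.70 ± 0.28 at MACIR, and 1.14 ± 0.08 and 0.52 ± 0.11 at IL3RA, in the authors' deposited table. These pairs differed by 8.92, 7.55 and 4.63 standard errors.

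Mutants inside genes were called in 60.6% of 523 constructs and intergenic mutants in 52.7% of 450 (two-sided Fisher's exact p = 0.0136, 0.0682 after adjustment over 5 tests). These constructs came from 200 and 163 regions, and constructs of a region are not independent of each other. Insertions and deletions were called in 57.5% and substitutions in 56.4% (two-sided Fisher's exact p = 0.857).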
